A study of Mus musculus with 8 samples.

How the data were processed

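Single cells of the mouse spinal cord were profiled by droplet sequencing of polyadenylated RNA (10x Genomics chemistry, per the layout and header of the files). Per the labels, 2-month-old C57BL/6 mice received an over-hemisection on the right side at T10, and a 1-cm segment around the lesion was taken. An equal segment came from uninjured mice. The tissue was digested with trypsin, filtered and spun before cells were loaded. There were 8 groups, uninjured and 0.5, 1, 3, 7, 14, 60 and 90 days after injury, each with 1 library. Per the labels each was pooled from 4 to 7 mice of both sexes. The mice were 61 days old in the uninjured and 0.5-day groups and 121 and 151 days old at 60 and 90 days, so time after injury and age cannot be separated at those times. The protocol text in the labels stops in mid-sentence, and its last sentence was not used here.

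The authors deposited UMI counts (unit: counts, no normalization) per gene and barcode, 1 matrix per library. Per the submitters' processing notes, Cell Ranger 2.1.0, STAR, Seurat 3.0.2 and the builds GRCm38.p6 and mm10 were used. Per the file headers, the matrices were written by Cell Ranger software version 3.0.1, so the sources give both versions. How barcodes were called as cells is not given in the sources used here. Every deposited barcode had at least 500 UMIs. Total UMIs per library were 16708355, 56620875, 106654395, 137576403, 129008437, 93156593, 68742750 and 92500564 from uninjured to 90 days, and median UMIs per barcode 1366.5, 2078, 5144, 8191.5, 6813, 8091.5, 7175.5 and 5053. Each file listed 27999 features, of which 27998 were Ensembl genes, and the last was GFP. No cell annotation was used here, so classes were rebuilt from the counts.

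All computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with 1 fixed random seed. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 92073 of 103446. Doublets were scored in each library by the share of simulated doublets among nearest neighbours, and the top 0.8% per 1000 barcodes was left out. That removed 9208 barcodes, from 4.93% to 13.4% of a library. Outside the 14-day library, cells with both Xist and a Y-linked UMI made up 5.41% to 23.3% of called doublets and 1.26% to 3.10% of kept cells. The 82865 kept cells were clustered together by Leiden at resolution 1 on a shared-neighbour graph (2000 variable genes, 30 principal components, 20 neighbours), with no batch correction.

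Clusters were called X-like from 8 to 12 markers per class, fixed for 16 classes before the data were examined. The class with at least 3 markers among the 10 leading genes of a cluster gave the name, and otherwise the class with the highest marker score. The score had to reach 0.4, with a margin of 0.1 over the next class unless 2 markers were among the leading genes. Clusters stayed unnamed with under 50 cells, under 3 detected markers, leading genes of myeloid precursors or of another class, or low depth without a leading marker. This rule and its thresholds were set after the names from a first rule had been seen, because the first rule left the main microglia-type cluster of 0.5 days (cluster 4, 5225 cells) unnamed. The first rule had also called cluster 27 ependymal, clusters 14 and 42 dendritic, cluster 25 macrophage and cluster 43 oligodendrocyte, and the final rule leaves these unnamed. Clusters 33, 44, 45 and 46, unnamed by the first rule, are OPC-, B/plasma-, fibroblast- and microglia-like by the final one. Results under the first rule are given as an alternative. Clusters 32 and 40 were also unnamed. No cluster was named dendritic, mural, Schwann or neuron.

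With 1 library per group there is no replicate and no test, p-value or standard error. Each class share carries an exact Clopper-Pearson 95% interval. For genes, the UMIs of a class were summed per library and divided by the class total without mitochondrial genes to give CPM. Ratios to the uninjured library carry exact conditional binomial 95% intervals. All intervals cover counting error only, neither the variation between mice nor between libraries. A count of 0 was set to a floor of 3 UMIs of the class, and the ratio is then written as at least that fold. This wording refers to the floor and is no 95% bound. The 95% lower limit lies below the printed fold, at 80.8-fold against 101-fold for Nes in astrocyte-like cells at 0.5 days. Classes with at least 30 cells in both libraries were compared. This left out astrocyte-like cells at 3, 14 and 60 days (5, 5 and 12 cells), ependymal-like cells at 0.5 and 14 days, OPC-like cells (oligodendrocyte precursors) at 3, 60 and 90 days, and endothelial-like cells from 3 days on.

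There were 24 gene lists fixed before the data were examined. They cover pan-reactive, A1, A2 and homeostatic astrocyte genes, neural progenitor and synaptogenic genes, homeostatic and disease-associated microglia, lysosome, blood-brain barrier, angiogenic endothelium, cilium and myelin. Run in every class were lists for proliferation, extracellular matrix, cholesterol synthesis, glycolysis, immediate early and heat shock genes, interferon response, both MHC classes, chemokines, metal and oxidative stress and lipid handling. A list is summarised by the median log2 ratio of members with at least 10 UMIs over both libraries, with counts under 3 set to 3. Beside it stand the percentile among 10000 random lists matched on expression and a range from 1000 redraws of the counts. List members are counted as higher or lower if the ratio is at least 2-fold and its interval excludes 1. Naming markers made up 11 of the 20 homeostatic astrocyte genes, 11 of the 14 homeostatic microglia genes, 3 of the 12 barrier genes, 2 of the 14 angiogenic, 6 of the 14 cilium and 1 of the 14 myelin genes.

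Genes were named by a rule fixed before the data were examined. It takes per class and time the 5 highest and 3 lowest ratios in astrocyte-like cells, or 3 and 2 in other classes. Such genes needed at least 50 UMIs over both libraries, 50 CPM in the higher one and an interval wholly beyond 2-fold. Their CPM inside the class had to be no lower than outside it, as a guard against free RNA. Mitochondrial, ribosomal, hemoglobin, sex-linked marker and unnamed genes were left out. The rule also takes up to 4 members per list farthest from a ratio of 1 and a fixed set of 9 astrocyte and 4 microglia genes. The text prints the fixed set in full, most genes of the first kind for the planned classes, and examples of the list members. Shares of cells with a UMI of a gene were read after thinning each cell to 1000 UMIs. Granule-gene shares are given unthinned and, for 60 and 90 days, thinned, and shares by sex-linked genes are unthinned.

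The ratio, its interval and the list percentile were tried on simulated counts. These were Poisson draws from the uninjured astrocyte-like profile at the class totals of uninjured cord and 0.5 days. Known folds of 2, 4 and 8 were recovered as log2 medians of 1.06, 2.02 and 2.91. The draws hold only the counting error that the intervals assume, so variation between cells, mice and libraries was not tested. Cell filters, doublet calls, clustering and naming were not tested either. The interval excluded 1 for 89.6% of genes at 2-fold and for 4.19% of unchanged genes. At 90 days, with 84 cells, it excluded 1 for 58.2% of genes at 2-fold. Of random lists with no simulated change, 6% fell outside percentiles 2.5 to 97.5.

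Alternatives planned before the data were examined were gene minimums of 200 and 1000, a mitochondrial limit of 10%, no doublet removal, Leiden resolution 2, median-ratio scaling, a pseudocount of 5 CPM, a free-RNA correction scaled to immune marker genes (planned for astrocyte-like cells, run in every class), female- or male-called cells alone, thinned cells and list members with at least 50 UMIs. Added later were the first naming rule, leaving out each gene's highest cell, list members that are not naming markers, and gene lists in oligodendrocyte-like cells.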

Results

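Astrocytes, immune cells and other cells of the mouse spinal cord were compared between uninjured cord and 7 times after a thoracic over-hemisection, from 0.5 to 90 days. Each of the 8 groups is 1 droplet library, pooled per the labels from 4 to 7 mice, so the comparisons describe libraries and carry no test. The libraries held 103446 barcodes, and 82865 cells remained after filters and doublet removal. Kept cells per library, from uninjured to 90 days, numbered 7864, 14489, 11135, 10986, 13949, 8737, 5864 and 9841. Depth differed strongly: median UMIs per kept cell were 1477 in uninjured cord, 2448 at 0.5 days, 5869 at 1 day and between 5071 and 8215 later. All intervals are 95% and cover counting error only.

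In uninjured cord, microglia-like cells made up 68.7% (67.7 to 69.7) of kept cells and astrocyte-like cells 18.9% (18.1 to 19.8). Myeloid cells were abundant early after injury. Macrophage/monocyte-like cells were 0.852% in uninjured cord, then 17.2%, 35.8% and 33.9% at 0.5, 1 and 3 days, and 8.22%, 3.43%, 3.92% and 1.47% from 7 to 90 days. Neutrophil-like cells went from 0.801% in uninjured cord to 20.8% and 28.5% at 0.5 and 1 day, 7.99%, 2.01% and 2.69% at 3, 7 and 14 days, and were 13.5% and 18.6% at 60 and 90 days. Microglia-like cells were 36.5%, 15.5% and 46.2% at 0.5, 1 and 3 days and 77.0%, 74.7%, 60.4% and 56.0% later. T/NK-like cells were 0.623%, 1.17%, 1.29%, 0.837% and 1.15% up to 7 days and 3.46%, 3.33% and 3.30% after. B/plasma-like cells were 1.14%, 5.69%, 1.92%, 1.12% and 0.710% up to 7 days and 5.63%, 11.6% and 7.16% after.

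**Figure D1:**
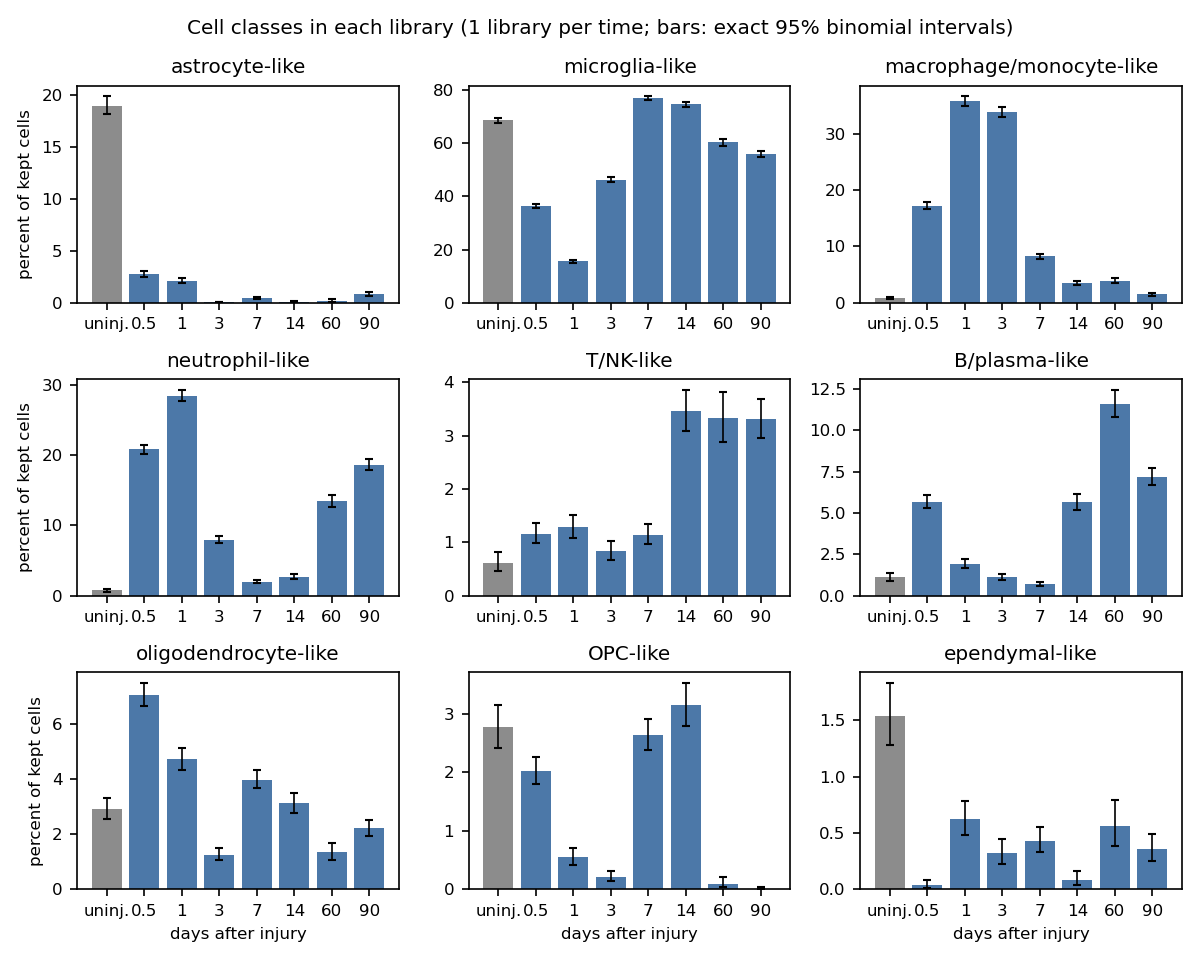
Percent of kept cells (y axis) in 9 cell classes against days after injury (x axis), with exact 95% intervals. Astrocyte-like cells are 18.9% in uninjured cord and at most 2.73% after injury, while neutrophil-like cells reach 28.5% at 1 day.

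Glia other than microglia took smaller shares. Oligodendrocyte-like cells were 2.91%, 7.07%, 4.71%, 1.26%, 3.98%, 3.12%, 1.35% and 2.22% from uninjured to 90 days. OPC-like cells (oligodendrocyte precursors) were 2.77%, 2.02%, 0.548%, 0.209%, 2.64%, 3.15% and 0.0853% up to 60 days, and none of 9841 cells at 90 days (upper limit 0.0375%). Ependymal-like cells were 1.54%, 0.0345%, 0.620%, 0.319%, 0.430%, 0.0801%, 0.563% and 0.356%. The first naming rule, which adds cluster 27, gives 2.32%, 2.73% and 0.601% at 0.5, 1 and 3 days. Endothelial-like cells were 0.750% in uninjured cord and 0.400%, 0.287%, 0.0546%, 0.143%, 0.160%, 0.136% and 0.0610% after injury. Fibroblast-like cells stayed between 0.0341% and 0.386%, and erythroid-like cells between 0.143% and 1.57%. Unnamed clusters held 0.458%, 5.93%, 7.77%, 7.26%, 2.85%, 2.77%, 4.21% and 8.39%. Among them, cluster 14, led by MHC class II genes and Cd209a, held 4.80% at 1 day and 6.53% at 3 days. Cluster 25, led by the granule protease genes Mpo, Elane and Prtn3, held 2.13% and 2.85% at 60 and 90 days.

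Few astrocytes were recovered after injury. Their share was 2.73% (2.47 to 3.00; 395 cells) at 0.5 days, 2.101% (1.84 to 2.39; 234) at 1 day, 0.452% (0.347 to 0.577; 63) at 7 days and 0.854% (0.681 to 1.06; 84) at 90 days. At 3, 14 and 60 days it was 0.0455%, 0.0572% and 0.205% (5, 5 and 12 cells), too few for expression. The uninjured share stayed the highest under a 1000-gene minimum, at 6.70%. A 200-gene minimum raised the shares at 3 and 7 days to 0.283% and 0.747%, and 3 days then lay above 14 days (0.123%) and 60 days (0.278%). The libraries ranked in a similar way against other glia: per 100 oligodendrocyte-like cells there were 651 astrocyte-like cells in uninjured cord and 38.5, 44.6, 3.62, 11.4, 1.83, 15.2 and 38.5 after injury.

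Positions of main genes (GRCm38) are Gfap (ENSMUSG00000020932, 11:102887336-102900912, minus strand), Hspb1 (ENSMUSG00000004951, 5:135887919-135889563, plus), Timp1 (ENSMUSG00000001131, X:20870166-20874735, plus) and Tm4sf1 (ENSMUSG00000027800, 3:57285611-57301988, minus). Slc7a10 is ENSMUSG00000030495 (7:35186385-35201114, plus), P2ry12 ENSMUSG00000036353 (3:59216272-59262871, minus) and Spp1 ENSMUSG00000029304 (5:104435118-104441050, plus).

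Within 1 day of injury, astrocyte-like cells carried a strong reactive program with stress, interferon and chemokine genes, and lower levels of several homeostatic genes. Immune genes reached 11.5% of the library level in this class in uninjured cord and 30.9%, 15.5%, 23.4% and 2.48% at 0.5, 1, 7 and 90 days. Immune RNA was therefore not excluded from its interferon and chemokine values. The pan-reactive list lay at a median log2 ratio to uninjured of 4.88 (redraw range 4.64 to 5.25) at 0.5 days and 5.84 (5.39 to 6.11) at 1 day. All 12 measured members were at least 2-fold higher, above all random lists. Here and below, list members are counted as higher or lower if the ratio is at least 2-fold and its interval excludes 1. The homeostatic list lay at -0.69 and -0.66 (percentile 0.03 at both), with 5 and 7 of 20 members at least 2-fold lower. Over all well-measured genes, the median log2 ratio was 0.22, 0.55, 0.45 and 0.42 at 0.5, 1, 7 and 90 days. Relative to it, the pan-reactive medians are 4.66 and 5.29 and the homeostatic ones -0.91 and -1.22.

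The highest genes at 0.5 days were Hspb1, a small heat shock protein (230-fold, 139 to 412), Timp1, an inhibitor of matrix proteases (535-fold, 94.8 to 21237, from 1 uninjured UMI), the stress transcription factor Atf3 (406-fold, 71.7 to 16153) and the secreted peptide precursor Vgf (at least 169-fold). Prg2 also met the rule (at least 808-fold), but all of its 848 UMIs came from 1 cell. At 1 day Hspb1 was 719-fold (435 to 1290) and Timp1 1114-fold (199 to 44091) higher. The membrane protein Tm4sf1 was at least 742-fold, the filamin Flnc 275-fold (75.2 to 2287) and Vgf at least 339-fold higher (57% of its UMIs in 1 cell). Lower were Phactr3 (13.6-fold), the ephrin receptor Epha4 (9.17-fold) and Tbc1d7 (7.92-fold) at 0.5 days, and the adhesion molecules Negr1 (16.1-fold) and Ntm (14.2-fold) and the carbonic anhydrase Car14 (14.8-fold) at 1 day.

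Both proposed reactive subtypes were higher together. The A1 list lay at 2.92 and 3.56 and the A2 list at 4.61 and 5.03 at 0.5 and 1 day, all members at least 2-fold higher. Examples are the interferon-induced GTPases Gbp2 (127-fold, 42.5 to 623) and Iigp1 (57.2-fold) at 0.5 days and the transglutaminase Tgm1 (at least 83.7-fold) at 1 day. Of the pan-reactive list, the hyaluronan receptor Cd44 was 90.1-fold (56.5 to 153) higher at 1 day. The interferon list lay at 3.56 and 3.26, with Ifit1 71.9-fold, Usp18 52.9-fold and Ifit3 48.6-fold higher at 0.5 days. MHC class I genes lay at 2.00 and 2.07, with the peptide transporter Tap1 10.6-fold higher at 0.5 days and H2-T23 4.19-fold at 1 day. Immediate early genes lay at 3.63 and 3.42, chemokines at 4.32 and 3.97, MHC class II at 2.70 and 3.99, and metal and oxidative stress genes at 1.75 and 1.46. Txnrd1, a thioredoxin reductase, was 12.1-fold higher at 1 day.

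Some of these genes were even higher outside the class, so free RNA from immune cells was not excluded as part of their signal. At 0.5 days this holds for Ccl2 (1490-fold, 266 to 58969), Cxcl2 (at least 573-fold), Ccl12 (427-fold), Ccl7 (at least 253-fold), Thbs1 (1090-fold, 194 to 43153), Srgn (79.6-fold), Srxn1 (34.0-fold), Egr1 (30.9-fold), Fos (21.6-fold), Junb (14.8-fold), Hmgb2 (7.64-fold) and Pcna (4.23-fold). At 1 day it holds for Hmox1 (170-fold), H2-Ab1 (26.7-fold), Cd74 (16.9-fold), Ftl1 (10.9-fold), Psmb8 (6.68-fold), Plin2 (5.71-fold) and Ldha (4.00-fold). After free-RNA correction the pan-reactive medians were 5.52 and 6.37. Homeostatic members moved separately: the gap junction gene Gja1 lay at -1.50 and -1.91, the amino acid transporter Slc7a10 at -1.88 and -1.76, the potassium channel Kcnj10 at -0.69 and -0.89, and glutamine synthetase (Glul) at -0.12 and -0.35.

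At 7 days, 63 astrocyte-like cells still carried the reactive program, now with matrix genes, while the cholesterol synthesis and homeostatic lists were lower. Not every homeostatic gene fell: Aqp4 was 3.53-fold higher (log2 ratio 0.96 with median-ratio scaling). The pan-reactive list lay at 5.69 (5.13 to 5.98), with 11 of 12 members higher and Cxcl10 lower (-1.11). The homeostatic list lay at -1.09 (-1.19 to -0.91; percentile 0), with 11 of 20 members at least 2-fold lower. Relative to all genes these are 5.25 and -1.54. A1 genes lay at 3.52 and A2 genes at 5.44. Matrix genes lay at 1.47 (percentile 99.7), with Timp1 1627-fold (289 to 64530; 42% of UMIs in 1 cell), Fn1, a fibronectin, at least 414-fold and Tnc, a tenascin, 119.5-fold higher (44.7 to 451). Hspb1 was 538-fold, Tm4sf1 at least 930-fold (30.5% in 1 cell), the pentraxin Ptx3 249-fold (66.6 to 2094) and Cd109 119.5-fold higher.

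Cholesterol synthesis lay at -2.55 at 7 days (-3.00 relative to all genes; 16 of 18 members lower), with Insig1 13.5-fold, Cyp51 9.10-fold, Dhcr7 7.65-fold and Mvd 7.50-fold lower. At 0.5 and 1 day that list was at -0.03 and -0.45. At 7 days it lay below 0 in microglia-, oligodendrocyte-, ependymal- and OPC-like cells too. Slc7a10 (23.7-fold, 16.8 to 34.7), the GABA transporter Slc6a11 (6.79-fold), the lipid receptor S1pr1 (4.70-fold) and the connexin Gjb6 (4.09-fold) were lower, as were B3galt2 (24.0-fold, 8.18 to 117) and the thyroid hormone transporter Slco1c1 (23.4-fold, 7.95 to 114). Gja1 lay at -1.30 and Glul at -0.83. The growth factor Vegfa was 9.85-fold and the glucose transporter Slc2a1 3.31-fold lower, with the glycolysis list at 0.02 (0.39 and 0.57 at 0.5 and 1 day).

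Progenitor genes split at 7 days: Id1 was 15.2-fold higher and Fabp7 lay at 2.33, while Msi1 was 8.58-fold and Hes1 6.09-fold lower. The list median was -0.47, 0.27 and 0.40 at 0.5, 1 and 7 days, and -0.28 and -0.05 relative to all genes at 1 and 7 days. Sox9 lay at 0.96, 0.52 and 0.84. Synaptogenic genes lay at -0.07, 0.41 and 0.88, with Thbs2 10.3-fold higher at 7 days, Fgf2 5.50-fold higher at 1 day and Ptn 4.62-fold lower at 0.5 days. Other lists at 7 days were immediate early 2.63, interferon 1.33, MHC class I 0.86 (H2-D1 5.63-fold), MHC class II 1.95, chemokine 2.41 and metal stress 1.77. Lipid handling lay at 0.22, 0.56 and 1.53, with Abca1, a cholesterol exporter, 10.9-fold and Lpl 36.8-fold higher at 7 days and Apoc1 7.28-fold lower at 1 day. After correction the list was 0.67 at 7 days, and Lpl and H2-D1 were higher outside the class. Matrix genes were at 0.39 and 0.64 at 0.5 and 1 day.

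At 90 days the 84 astrocyte-like cells resembled uninjured ones in both main lists. The pan-reactive list lay at 0.37 (-0.14 to 0.80, percentile 45.8), -0.05 relative to all genes. Under the alternatives it ranged from -0.80 with a minimum of 1000 genes to 1.12 with thinned cells, so its sign is not settled. Serpina3n, a protease inhibitor high at 0.5 to 7 days (4.40, 4.91 and 5.55), was at -2.18. The homeostatic list lay at 0.45 (0.39 to 0.52), 0.03 relative to all genes, with Slc7a10 at 0.18, Gja1 at 0.40 and Glul at 0.94. Interferon genes stayed higher: that list lay at 1.40 (percentile 100; 0.97 relative), with 5 of 11 members counted as higher. Higher genes were the cytochrome Cyp4f14 (4.79-fold, 2.76 to 8.17), Zfp397 (4.43-fold), Agfg1 (4.10-fold) and Aig1 (3.99-fold). Ccl5 was 46.9-fold higher, with 98.1% of its UMIs in 1 cell. Lower were Ttll4 (8.75-fold, 2.95 to 42.8), the retinoic acid enzyme Aldh1a3 (8.42-fold, 2.84 to 41.2) and Mitd1 (6.63-fold, 2.22 to 32.6), each with 3 UMIs, Hk2 (3.71-fold) and H2-DMa (7.62-fold, 1.31 to 307, 1 UMI). Relative to uninjured, other medians were A1 0.90, A2 0.36, matrix 0.50, progenitor 0.14, cholesterol 0.13, glycolysis 0.65, immediate early -0.27, MHC class I 0.90, MHC class II 1.57, chemokine 0.67, metal stress 0.62, synaptogenic 0.19 and lipid 0.09. A2, progenitor, cholesterol, synaptogenic and lipid medians fall below 0 relative to all genes.

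**Figure D2:**
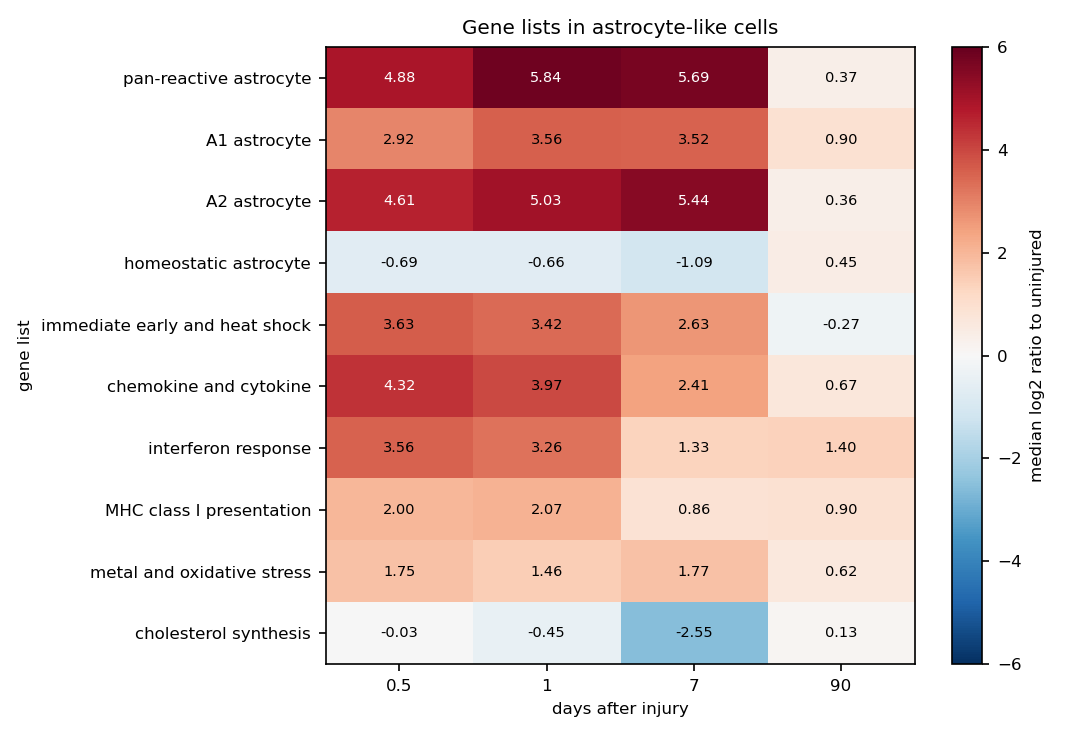
Median log2 ratio to uninjured (colour and printed value) of 10 gene lists in astrocyte-like cells at 0.5, 1, 7 and 90 days (columns). The pan-reactive row reads 4.88, 5.84, 5.69 and 0.37, and the cholesterol row -0.03, -0.45, -2.55 and 0.13.

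Gfap, the classic filament of reactive astrocytes, was 7.59-fold (6.84 to 8.43) higher at 0.5 days, 16.8-fold (15.3 to 18.5) at 1 day and 23.8-fold (21.5 to 26.3) at 7 days. At 90 days it was 0.792-fold (0.590 to 1.05), with 182 against 230 CPM in uninjured cord. After thinning to 1000 UMIs, 11.95% of astrocyte-like cells held a Gfap UMI in uninjured cord, and 60.1%, 85.1%, 96.5% and 11.9% after 0.5, 1, 7 and 90 days. Unthinned these were 17.3%, 73.4%, 92.3%, 96.8% and 40.5%, with 101, 47, 33, 6 and 0 cells left out by thinning. Background in thinned microglia-like cells was 7.09%, 5.04%, 3.23%, 1.67% and 0.695%. Median UMIs were 1455.5, 1732, 2881, 4129 and 3833 in astrocyte-like and 1431, 2368, 10135, 6644 and 4459 in microglia-like cells.

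Vim, another filament, was 27.2-fold, 133-fold and 344-fold (239 to 516) higher at 0.5, 1 and 7 days and 1.95-fold at 90 days. At 0.5 days its level lay below that outside the class (362 against 1220 CPM), and free-RNA correction turned the log2 ratio to -0.44. At 1 and 90 days it also lay below (1773 against 1853 and 26.0 against 616 CPM). Its share at 7 days was 78.9% against 11.6% in microglia-like cells. Nes, a progenitor filament, had no uninjured UMI and was at least 101-fold, 144-fold and 86.3-fold higher at 0.5, 1 and 7 days, with none in either library at 90 days. Its thinned share at 0.5 days was 7.76%, against 8.61% in microglia-like and 1.66% in neutrophil-like cells, and its level lay above that outside the class (139 against 72.5 CPM). At 1 and 7 days the shares were 17.4% and 14.0%, against 8.06% and 1.65% in microglia-like cells. The complement gene C3 was 3.22-fold, 7.01-fold and 92.2-fold (60.9 to 146) higher, with 47.4% of cells at 7 days against a background of 2.26%, and a single UMI at 90 days (0.295-fold, 0.00718 to 1.81). At 0.5 days its level lay below that outside the class (35.4 against 85.8 CPM), and 23.8% of thinned neutrophil-like cells held it against 2.30% of astrocyte-like ones. Lcn2 was 31.9-fold and 46.9-fold higher at 0.5 and 1 day, 3.64-fold at 7 days and 5.40-fold at 90 days. Outside the class it was higher at 0.5, 7 and 90 days (5824 against 104 CPM at 90 days). With a 1000-gene minimum its log2 ratio turned to -0.68 at 7 days and -0.043 at 90 days.

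**Figure D3:**
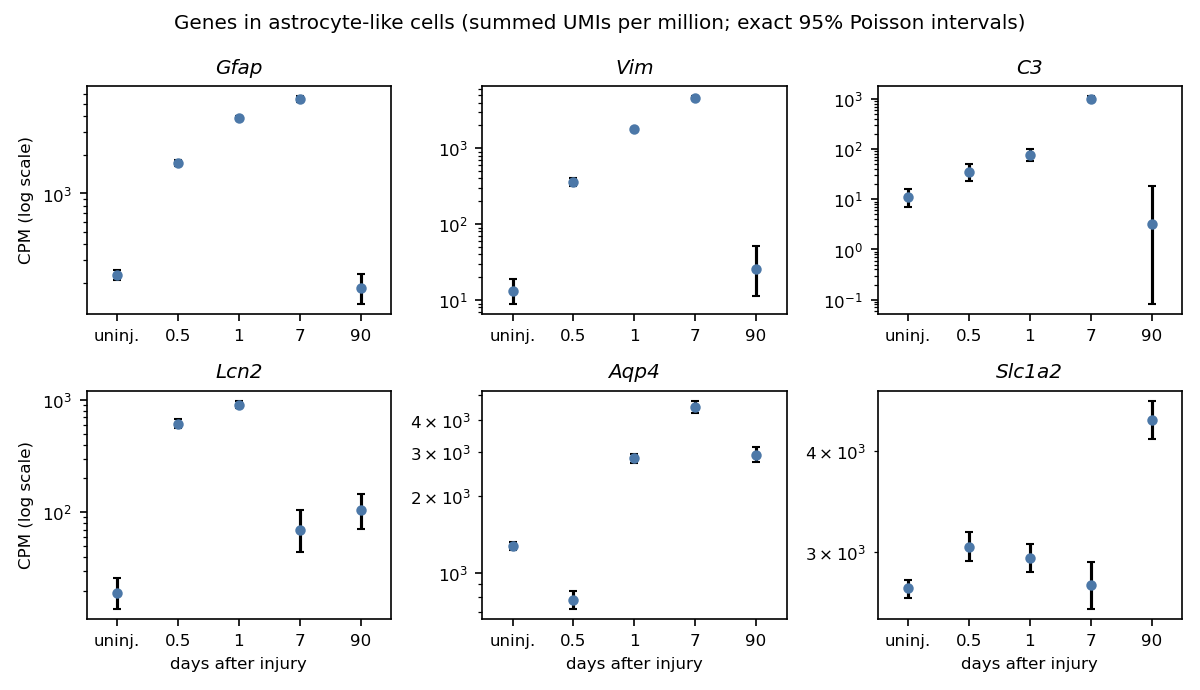
CPM (log y axis) of Gfap, Vim, C3, Lcn2, Aqp4 and Slc1a2 in astrocyte-like cells of uninjured cord and 0.5, 1, 7 and 90 days (x axis), with exact 95% Poisson intervals. Gfap goes from 230 to 5466 at 7 days and 182 at 90 days.

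Aqp4, the water channel, was 0.615-fold (0.562 to 0.672) at 0.5 days and 2.22-fold, 3.53-fold and 2.29-fold at 1, 7 and 90 days. The glutamate transporter Slc1a2 was near level (1.13-fold, 1.09-fold and 1.01-fold) and 1.61-fold (1.52 to 1.71) at 90 days, and median-ratio scaling put its log2 ratio at -0.16, -0.46, -0.85 and 0.30. S100b was at 0.998-fold, 0.867-fold, 0.906-fold and 0.857-fold, or at log2 ratios of -0.33, -0.79, -1.01 and -0.61 with that scaling. Division was left open by low counts: Mki67 had 2 UMIs in uninjured cord and 2, 3, 1 and 1 after injury (2.86-fold, 0.207 to 39.5; 4.01-fold, 0.459 to 48.0; 3.32-fold, 0.0563 to 63.8; 3.54-fold, 0.0600 to 68.0), while the proliferation list lay at 1.78, 1.54, 1.87 and 0.66, with 3 of 7, 5 of 7, 6 of 8 and 0 of 5 members counted as higher. Requiring 1000 genes per cell left 95 uninjured astrocyte-like cells and lowered the pan-reactive medians to 3.50, 3.60, 3.27 and -0.80. Gfap, Aqp4, Slc1a2, Hspb1 and Clu lead cluster 26, which holds 84.6%, 91.9% and 92.1% of the class at 0.5, 1 and 7 days. Cluster 15 holds 98.3% in uninjured cord and all at 90 days. The split at 90 days depends on the gene filter. With a minimum of 200 genes, a cluster led by Clu, Aqp4, Gfap and Hspb1 held 25 astrocyte-like cells at 90 days. The other astrocyte-like cluster then held 83. In uninjured cord they held 87 and 1720 cells.

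Microglia-like cells at 0.5 days traded their resting signature for chemokines, cytokines and stress genes. The homeostatic list lay at -2.57 (percentile 0; 13 of 14 members at least 2-fold lower). The purinergic receptor P2ry12 was 38.9-fold, Tmem119 7.91-fold, Gpr34 50.3-fold (44.3 to 57.4), the fructose transporter Slc2a5 128-fold (64.6 to 298) and Crybb1 17.7-fold lower. The chemokine list lay at 4.88, with 16 of 17 members higher: Cxcl2 4766-fold (1631 to 23113), Ccl7 at least 1863-fold, Ccl2 344-fold and Ccl3 84.2-fold. Cxcl2 was higher still outside the class. Of genes highest within it, neuropeptide Y (Npy) led at 3054-fold (845 to 25219), with Ccl7 and the interleukin-1 receptor antagonist Il1rn (749-fold, 479 to 1240). Metal stress lay at 2.49, with the cystine transporter Slc7a11 102-fold and Srxn1 26.3-fold higher, and interferon genes lay at 1.98 (Rsad2 31.2-fold, Ifit1 15.8-fold, Isg15 9.29-fold). Msr1, a scavenger receptor, was 580.1-fold and Ch25h, a cholesterol hydroxylase, 185.5-fold higher. The heat shock genes Hspa1a and Hspa1b were 58.6-fold (19.9 to 286) and 42.1-fold (14.2 to 206) higher and Slc2a1 6.85-fold, while the proteasome gene Psmb9 was 4.48-fold lower. Cluster 4 holds 98.9% of the class at 0.5 days and is led by Ccl12, Il1rn, Ccl3, Ccl4, Cd14 and Tnf, so it may be that library more than a type.

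At 1 and 3 days microglia-like cells carried genes of cell division. The proliferation list lay at 4.63 and 5.84, all 18 members higher, after 0.88 at 0.5 days. Mki67 was 248-fold higher at both times (114 to 676 at 1 day), Rrm2 235.5-fold (80.5 to 1143) at 1 day, and Cdca3 257-fold (87.8 to 1245), Ccna2 174-fold (59.6 to 846) and Birc5 173-fold at 3 days. Spp1, osteopontin, was 47.9-fold, 404-fold and 903-fold (825 to 990) higher at 0.5, 1 and 3 days, though its CPM outside the class was higher still at 1 day (29533 against 22653) and 3 days (71643 against 50624). Fn1 was 551-fold (361 to 891) and heme oxygenase Hmox1 166-fold higher at 3 days, the scavenger receptor Cd36 45.1-fold, Pgam1 7.84-fold and Pkm 6.98-fold. Msr1 was 311-fold higher at 1 day. Siglech was 16.2-fold lower at 1 day, Cd27 23.4-fold and 18.98-fold and Sult1a1 17.1-fold and 15.5-fold lower at 1 and 3 days, and Mertk, an engulfment receptor, 3.91-fold lower at 3 days. Cluster 13, led by Mki67 and Top2a, holds 18.4% and 17.7% of the class at these times.

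From 7 to 90 days, the lipid-handling and disease-associated lists lay higher in the class as a whole. The disease-associated list lay at 0.16, 1.12 and 1.59 at 0.5, 1 and 3 days and at 3.22, 3.45, 3.14 and 2.80 from 7 to 90 days, with 12, 12, 12 and 11 of 15 members higher. Lipid handling lay at 1.15, 1.00, 1.22, 3.06, 3.01, 2.496 and 2.12. Apoe was 0.478-fold, 0.345-fold and 1.60-fold at 0.5, 1 and 3 days, with more CPM outside the class at 1 and 3 days, and 11.9-fold, 14.0-fold, 16.3-fold and 14.9-fold from 7 days. Spp1 was 242-fold, 138-fold, 123-fold and 103-fold higher. The first naming rule turns Apoe at 0.5 days to a log2 ratio of 1.13. At 7 days the macrophage protein Cd5l was at least 471-fold, Fn1 247-fold and the growth factor Igf1 70.45-fold higher. At 14 days Apoc4 was 254-fold, the scavenger collectin Colec12 150-fold and the receptor kinase Axl 3.83-fold higher. At 60 and 90 days the glycoprotein Gpnmb was 1341-fold (681 to 3110) and 860.1-fold, the peroxidase Gpx3 391-fold (108 to 3232) and 302-fold (83.5 to 2494) and Apoc4 346-fold and 232-fold higher. At 60 days the proton pump subunit Atp6v0d2 was at least 255-fold, Apoc1 53.5-fold and galectin-3 (Lgals3) 31.6-fold higher.

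The resting signature stayed low throughout. The homeostatic list lay at -2.05, -1.99, -1.98, -1.88, -1.75 and -1.33 from 1 to 90 days, each at percentile 0. The median over all genes was 0.12, 0.16, -0.07, -0.42, -0.33, -0.35 and -0.29 from 0.5 days, and relative to it the list lay at -2.70, -2.21, -1.92, -1.56, -1.55, -1.39 and -1.04. P2ry12 was 8.25-fold, 3.87-fold, 5.95-fold, 6.23-fold, 3.49-fold and 2.32-fold lower from 1 to 90 days, and Tmem119 3.63-fold, 5.02-fold, 5.90-fold, 7.18-fold, 5.33-fold and 3.48-fold. Gp9, a platelet glycoprotein gene, was 14.5-fold, 19.7-fold, 12.2-fold and 8.48-fold lower from 7 to 90 days, and Cd27 14.7-fold, 13.3-fold, 7.44-fold and 6.32-fold. Cluster 0, led by P2ry12 and Tmem119, holds 94.7% of the class in uninjured cord, 24.3% at 60 days and 31.0% at 90 days. Cluster 3, led by P2ry12, Siglech and Gpr34, holds 24.5% at 3 days, 24.4% at 7 days, 7.49% at 14 days, 19.8% at 60 days and 25.5% at 90 days. Clusters 1 (led by Apoc1, Apoc4 and Cd5l) and 2 (led by Cst7 and Lpl) hold most at 7 and 14 days, and cluster 1 holds 31.9% and 23.4% at 60 and 90 days.

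Antigen presentation came late in microglia-like cells. MHC class II genes lay at 0.85, 0.20, -0.04 and -0.27 up to 7 days and 2.24, 2.75 and 2.65 at 14, 60 and 90 days. H2-Aa was 28.6-fold (22.2 to 37.5), H2-Eb1 26.7-fold, their activator Ciita 19.1-fold (3.35 to 765) and H2-Ab1 10.2-fold higher at 60 days, all with more CPM outside the class. Cluster 17, led by these genes, holds 14.8% and 11.5% of the class at 60 and 90 days. MHC class I lay at -0.22, -0.28, -0.13, 0.34, 0.76, 0.81 and 0.67, with H2-D1 4.83-fold and H2-K1 4.22-fold higher at 14 days and Nlrc5 3.42-fold at 60 days. Interferon genes lay at 1.18, 1.67, 1.03, 1.13, 0.63 and 0.89 from 1 day, with Gbp2 9.90-fold higher at 60 days. With male-called cells alone the list turned to -0.14 and -0.62 at 60 and 90 days.

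**Figure D4:**
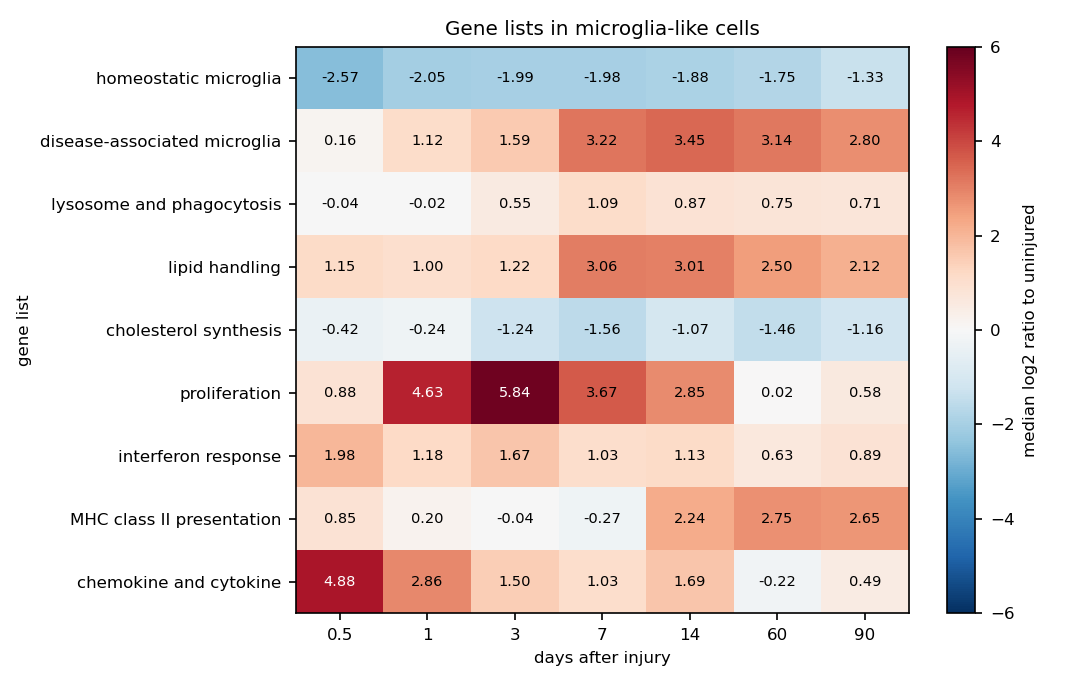
Median log2 ratio to uninjured (colour and printed value) of 9 gene lists in microglia-like cells (y axis) at 7 times after injury (columns). The homeostatic row stays between -2.57 and -1.33, and the disease-associated row goes from 0.16 to 3.45 at 14 days.

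Metabolic and clearance lists moved as well in microglia-like cells. Lysosome genes lay at -0.04, -0.02, 0.55, 1.09, 0.87, 0.75 and 0.71 from 0.5 to 90 days. Cholesterol synthesis lay at -0.42, -0.24, -1.24, -1.56, -1.07, -1.46 and -1.16, with Fdft1 5.48-fold and Lss 5.21-fold lower at 7 days. Glycolysis lay at 1.36, 1.39, 1.44, 0.24, 0.72, 0.56 and 0.35, while Vegfa was 10.2-fold lower at 7 days. Immediate early genes lay at 1.44, 1.77, 0.05, 0.62, 1.77, -0.86 and -0.80, with the phosphatase Dusp1 24.5-fold and Fosb 17.1-fold higher at 14 days. That list was higher at 14 days in other classes too: oligodendrocyte-like 2.09, B/plasma-like 1.63, neutrophil-like 1.31, T/NK-like 1.10 and macrophage/monocyte-like 0.88. Proliferation was 3.67, 2.85, 0.02 (1 of 18 members higher and 1 lower) and 0.58 from 7 days, the last turning to -0.31 with male-called cells alone. Chemokines lay at 2.86, 1.498, 1.03, 1.69, -0.22 (0.13 relative to all genes) and 0.49 from 1 day, the last turning to -0.17 with 1000 genes and -0.19 with male-called cells alone. Metal stress lay at 1.43, 1.11, 0.36, 0.45, 0.58 and 0.58. The matrix list lay at 0.22, 0.34, -0.32, -0.98, -1.20, -1.64 and -1.62. Its lowest members, Ncan (321-fold, 55.7 to 12850), Ptprz1 (222-fold) and Bcan (163-fold), are astroglial or OPC genes, as are Clu (173-fold) and Mt3 (69.6-fold). All 5 had higher CPM outside the class, so free RNA from other cells was not excluded as their source.

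Ependymal-like cells were named in part by cilium genes, so the cilium list says little about loss of that program. It lay at -0.18, 0.10, -0.16, 0.28 and -0.08 at 1, 3, 7, 60 and 90 days. Single members were lower: Ccdc153 2.25-fold at 1 day, Tmem212 2.20-fold and the cilium regulator Foxj1 2.19-fold at 90 days. The cytokine brake Socs3 was 29.9-fold (10.1 to 146) higher at 1 day and S100a6 24.3-fold and 4.33-fold at 1 and 7 days. The complement inhibitor Serping1 was 85.7-fold (14.8 to 3442, from 1 UMI) and Hspb1 17.7-fold higher at 3 days, the clock gene Dbp 4.32-fold at 7 days and the chaperone Cryab 4.70-fold at 60 days. Tagln (7.88-fold) and Aqp4 (4.14-fold) at 60 days rest on 1 cell for 43.3% and 70.2% of UMIs. Lower were the noncoding RNA Snhg9 (15.1-fold, 9.25-fold, 9.31-fold and 4.47-fold at 1, 3, 7 and 60 days), Snhg20 (6.15-fold at 1 day), Clec3b (10.98-fold and 9.67-fold at 3 and 90 days), Cd27 (8.33-fold and 5.93-fold at 7 and 60 days) and Timp3 (10.6-fold, 3.44 to 52.7, at 90 days).

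MHC class I genes in ependymal-like cells lay at -0.15, -0.48, 0.97, 0.98 and 2.21, with H2-D1 6.25-fold and H2-K1 4.32-fold higher at 90 days. Both had more CPM outside the class (1467 against 1146 and 706 against 522), with 30.4% and 23.6% of UMIs in 1 cell. Apoc1, Plac8 and Lpl at 90 days (68.4-fold, 26.1 to 254; 173-fold, 30.3 to 6907; 23.8-fold, 9.69 to 75.8) come mostly from 1 cell each. MHC class II lay at 0.69, -0.89, -0.59, -1.50 and 2.26 (0.97 without the highest cell). Immune genes reached 26.0% of the library level in this class in uninjured cord. At 1, 3, 7, 60 and 90 days they reached 5.61%, 3.00%, 34.0%, 9.83% and 12.9%. Immune RNA in the uninjured cells was therefore not excluded as a source of lower immune-gene values. Other medians at the same times were interferon 0.97, 1.30, 0.54, 0.19 and 0.53 (Ifitm3 3.02-fold at 3 days), chemokine 1.03, -1.25 (1 member), 2.20, 0.51 (2 members) and 2.66, and immediate early 1.20, -0.77, 0.90, -0.79 and 0.15 (Fos 7.79-fold at 1 day). Metal stress lay at 0.80, 0.61, 0.61, 0.69 and -0.16, lipid handling at -0.76, -0.76, 2.09 (0.41 after correction), 0.78 and 1.25, and matrix at -0.04, -0.46, -0.06, 0.04 and -1.69. Cholesterol lay at 0.24, -0.45, -0.91, -0.68 and -0.52, glycolysis at 0.29, -0.08, 0.15, 0.39 and 0.11, and proliferation at 0.14, 0.08, 0.32, 0.87 and 0.58 from 2 to 7 members. These libraries hold 33 to 69 such cells after injury. Cluster 27, which the first naming rule called ependymal, is not among them. It is led by Tm4sf1 and Stmn2 and held 235 and 31 cells at 1 and 3 days.

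OPC-like cells had higher interferon, chemokine and immediate early genes at 0.5 days, and division genes were higher at 7 days. Cluster 24, led by Tnr and Gpr17, holds 78.4% of the class in uninjured cord. At 0.5, 1, 7 and 14 days it holds 77.1%, 65.6%, 66.3% and 69.5%. Cluster 33, led by Cspg5, Ptprz1 and C1ql1, holds the rest, so a changed mix was not excluded from the list values. The first naming rule leaves cluster 33 unnamed. The interferon list lay at 3.27, 1.84, 0.28 and 0.42 at 0.5, 1, 7 and 14 days, with Usp18 35.4-fold (9.61 to 295) and Bst2 34.4-fold higher at 0.5 days. MHC class I lay at 2.07, 1.49, 0.60 and 0.70 (Tap1 19.5-fold, 6.49 to 95.7, at 0.5 days). The proliferation list lay at -0.67, 0.34, 1.69 and 0.54, with Cdc20 9.57-fold (3.63 to 35.8), Ube2c 7.28-fold and Birc5 7.21-fold higher at 7 days. Its value at 0.5 days changes sign with female-called cells alone (0.97), with the first naming rule (0.79) or with better-counted members (0.42). With female-called cells alone, proliferation, MHC class I and MHC class II at 14 days lay at -0.028, -0.19 and -0.23. Serpina3n was 377-fold (104 to 3110), 606.5-fold (167 to 5015), 149-fold (41.0 to 1230) and 36.5-fold (9.97 to 303) higher at these times. The complement gene C4b was at least 87.4-fold, 69.7-fold and 50.8-fold higher at 1, 7 and 14 days. At 0.5 days Vgf was at least 62.3-fold and the stress gene Gadd45g 43.5-fold higher, and at 1 day the Wnt modulator Sfrp1 177-fold (48.6 to 1470). S100a10 was 19.8-fold higher at 7 days and the synaptotagmin Syt4 8.03-fold at 14 days.

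Myelin genes in OPC-like cells lay at -0.75 (percentile 0), -0.01, -0.24 and 0.10, with Mal 3.96-fold and Bmp4 2.91-fold lower at 0.5 days and Opalin 4.41-fold higher at 1 day. Cholesterol synthesis lay at -0.02, -0.24, -0.83 and -0.94, with Dhcr7 3.37-fold lower at 14 days and Hsd17b7 4.41-fold higher at 0.5 days. Lower genes were Nfe2l3 (6.22-fold) and Fkbp15 (4.40-fold) at 0.5 days, Snhg9 (9.47-fold, 6.39-fold and 9.55-fold) from 1 day, Phpt1 (7.74-fold) at 1 day and Isg15 (11.8-fold and 6.55-fold) at 7 and 14 days. Other medians were immediate early 2.27, 2.31, 1.66 and 1.82 (Fos 34.3-fold at 0.5 days), chemokine 3.87, 2.70, 0.62 and 0.51, MHC class II 0.03, 2.26, 0.37 and 1.27, and metal stress 1.32, 0.80, 0.42 and 0.36. Chemokines at 7 days turned to -0.11 with female-called cells, -0.021 with male-called cells and -0.41 with thinned cells. Lipid handling lay at 0.91, 0.33, 1.84 and 0.80 (0.51 at 7 days after correction), matrix at 0.18, 0.24, 0.17 and 0.17, and glycolysis at 0.42, 0.63, 0.01 and 0.18.

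Endothelial-like cells, compared at 0.5 and 1 day with 58 and 32 cells, had lower barrier genes and higher matrix and glycolysis genes. Immune genes reached 34.2%, 42.6% and 40.9% of the library level in this class in uninjured cord, at 0.5 and at 1 day, so immune RNA was not excluded from its values. The barrier list lay at -1.28 (percentile 0.03) and -1.03, with 8 and 6 of 12 members at least 2-fold lower. Slco1c1 was 6.34-fold and the efflux pump Abcb1a 2.66-fold lower at 0.5 days, and the transferrin receptor Tfrc 2.75-fold and tight-junction Cldn5 2.35-fold lower at 1 day. Matrix genes lay at 1.83 and 1.21, with the collagens Col4a2 12.5-fold and Col4a1 4.40-fold higher at 0.5 days. Lcn2 was 189-fold (52.1 to 1568) higher at 0.5 days. Ptn was 57.2-fold (19.2 to 281) and 7.32-fold lower, Spock2 34.7-fold lower at 0.5 days and Car4 9.76-fold lower at 1 day, and AA467197 at least 12.5-fold higher at 1 day. Cxcl13 and Cxcl2 at 0.5 days (at least 46.7-fold and 78.6-fold) and Pf4 and Apln at 1 day (83.9-fold, 14.9 to 3331, and 43.1-fold, 7.55 to 1720) rest mainly on 1 cell each. The angiogenic list lay at 1.28 and 0.56 (-0.87 without the highest cell at 1 day, and -1.11 at 0.5 days with better-counted members), with Vwf 6.37-fold higher and Flt1 2.19-fold lower at 1 day and Cd34 2.90-fold lower at 0.5 days. Glycolysis lay at 0.78 and 1.55 (Pkm 5.93-fold), chemokines at 4.05 and 2.35 (3.19 and 1.36 after free-RNA correction), metal stress at 1.81 and 1.39 (Mt2 6.53-fold at 0.5 days), interferon at 0.14 and -1.11, immediate early at 0.30 and 0.18, lipid at 0.35 and 0.63, MHC class I at 0.02 and -0.53, MHC class II at 2.02 and 2.89 (1 member each), cholesterol at -0.77 and -0.69, and proliferation at 0.14 (1 member) and 1.01.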

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

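All 6 tests of explanations in this part were chosen after the results they measure had been seen.

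The first results listed here are gene lists whose median lies on opposite sides of 0 at different times after injury in the same cell class. With 1 library per time, none of these differences between times was tested. In OPC-like cells the proliferation list was at -0.67 at 0.5 days and at 1.69 and 0.54 at 7 and 14 days. The value at 0.5 days turns to 0.97 with female-called cells alone, 0.79 with the first naming rule and 0.42 with better-counted members. The value at 14 days turns to -0.028 with female-called cells alone. In microglia-like cells the immediate early and heat shock list was at 1.44, 1.77, 0.62 and 1.77 at 0.5, 1, 7 and 14 days and at -0.86 and -0.80 at 60 and 90 days. At 14 days it was higher in other classes too, with 2.09 in oligodendrocyte-like, 1.82 in OPC-like, 1.63 in B/plasma-like, 1.31 in neutrophil-like, 1.10 in T/NK-like and 0.88 in macrophage/monocyte-like cells. At 60 and 90 days it was 0.95 and 0.82 in oligodendrocyte-like, 0.37 and 0.20 in B/plasma-like, 0.30 and -0.42 in macrophage/monocyte-like, 0.45 and -1.22 in neutrophil-like and -0.40 and -0.32 in T/NK-like cells. In ependymal-like cells that list was at 1.20 and 0.90 at 1 and 7 days and at -0.77 and -0.79 at 3 and 60 days. Also in ependymal-like cells, MHC class II genes were at -1.50 at 60 days and 2.26 at 90 days. The latter rests on 4 members, with most UMIs of H2-Ab1 and Cd74 (90.9% and 86.7%) in 1 cell, and is 0.97 without the highest cell of each gene. For the value at 60 days, immune RNA in the uninjured cells was not excluded. Immune genes reached 26.0% of the library level there, against 9.83% at 60 days. Lipid handling genes in that class were at -0.76 at 1 day and 2.09, 0.78 and 1.25 at 7, 60 and 90 days. The value at 7 days falls to 0.41 after free-RNA correction, and at 90 days at least 52% of the UMIs of Apoe, Apoc1, Lpl and Fabp5 came from 1 cell per gene. In oligodendrocyte-like cells matrix genes were at 0.89 and 0.90 at 7 and 14 days and at -0.73 at 90 days. Cluster 39, led by Nfasc, Grb14 and Tspan2, is 32.4% and 12.8% of that class at 7 and 14 days, 0.873% in uninjured cord and absent at 90 days.

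Astrocyte-like cells made up under 0.5% of kept cells at 3, 14 and 60 days, and 0.452% at 7 days. Dilution by immune cells as the whole cause is argued against, since the share of astrocyte-like cells among all macroglia-like cells was 72.4% in uninjured cord and at most 9.30% in those 3 libraries. Loss at the gene filter or in clustering as the whole cause is argued against as well. Among all deposited barcodes at equal depth, 18.8% carried 4 or more astrocyte markers in uninjured cord and at most 0.347% in those 3. Of these naming markers, 11 are in the homeostatic list, which lay lower at 0.5, 1 and 7 days, so reactive cells may be undercounted. The gene filter did remove some cells: a 200-gene minimum raised the share at 3 days from 0.0455% to 0.283%. What stays open is a poorer release of scar-bound astrocytes from the tissue before capture, and a true loss of astrocytes at the lesion. Neither was tested, so the shares may describe the digestion more than the cord.

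Neutrophil-like cells were 13.5% and 18.6% of kept cells at 60 and 90 days, weeks after the early wave. A candidate explanation is that cells of marrow type entered these preparations. Of neutrophil-like cells, at least 79.7% at both times carried 3 or more granule genes of immature neutrophils (Camp, Ngp, Ltf and Fcnb), against 15.3%, 4.36% and 17.9% at 0.5, 1 and 3 days. It was 82.5% in uninjured cord and 83.6% and 81.7% at 7 and 14 days, so the share is near 80% in every library outside 0.5 to 3 days. In microglia-like cells it was at most 0.0914%, and thinning to equal depth gave 74.5% and 72.0% at 60 and 90 days. Clusters led by pre-B, myeloid precursor or erythroid genes took 9.96% and 9.67% of kept cells at 60 and 90 days, against 0.483% in uninjured cord. From 0.5 to 14 days they took 4.06%, 1.58%, 1.34%, 0.796% and 4.49%. The same granule count was set against mature neutrophils as the whole source. It cannot decide this, since the stage of granule-positive cells was not tested and the share is near 80% in uninjured cord as well. Neutrophil-like cells without 3 granule genes were at most 3.41% of kept cells at 60 and 90 days. Both readings rest on the same bound, so they are not independent, and Camp, Ngp and Ltf are also naming markers. Cluster 11, led by Retnlg, Mmp8 and Mmp9, holds 61.2% and 58.2% of the class at 60 and 90 days. The stage of its cells was not tested. Whether cells of marrow type came from vertebral marrow at dissection or from blood was not tested. This series holds no age-matched uninjured library for 60 and 90 days.

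The 14-day library held 1 Y-linked UMI (Ddx3y, Eif2s3y, Kdm5d and Uty) although its label names 3 male mice. Too little depth is argued against, since the lowest level of the other libraries would give 3188 such UMIs. Cells of female mice alone would give what was seen: 92.2% of kept cells held an Xist UMI and 0.0114% a Y-linked one. The label may therefore not describe the animals loaded. Sex and time are confounded at 14 days, and which animals were pooled was not tested. The uninjured library, the reference of every ratio, differed in sex mix too. Among its cells with either Xist or Y-linked UMIs but not both, 18.8% held Y-linked UMIs. In the injured libraries apart from 14 days this was 31.1% to 59.6%. Sex mix therefore differs in every ratio to uninjured unless female- or male-called cells are taken alone. No biological explanation was tested.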

How the results depend on the processing

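The first naming rule, leaving out the highest cell of each gene, and the restriction to list members that are not naming markers were chosen after the results had been seen. The other alternatives were planned, the free-RNA correction for astrocyte-like cells only. None was planned for oligodendrocyte-like cells, a class added later. In astrocyte-like cells the pan-reactive list stayed above 0 under every alternative run at 0.5, 1 and 7 days (3.50 to 5.93, 3.60 to 6.37 and 3.27 to 6.21), and at 90 days it ranged from -0.80 to 1.12. The homeostatic astrocyte list stayed below 0 at 0.5, 1 and 7 days (-1.02 to -0.34, -1.25 to -0.47 and -1.96 to -0.85) and above 0 at 90 days (0.064 to 0.61). The homeostatic microglia list stayed below 0 at all 7 times under every alternative run. Of 624 values of class shares under alternatives, 457 were the same within counting error and 167 moved. Of 4528 values of gene lists, 3373 were the same, 1129 moved and 26 were reversed. Reversed means that the sign changed and the main value was clear of 0. For a list, the percentile of the main value among the random lists also had to be extreme. Other changes of sign are not in this count. Of 671 values of single genes, 378 were the same, 282 moved and 11 were reversed. Depth limits the uninjured library most: with a minimum of 1000 genes only 95 of its astrocyte-like cells remain, and at 90 days a 2-fold difference is resolved for 58.2% of simulated genes.

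For the astrocyte-like share, the pan-reactive list, both homeostatic lists and the microglia-like share at 0.5 days, values that moved beyond counting error follow by setting. Other moved values are only counted above. Unless the construction shows it, the cause was not tested. With a minimum of 1000 genes the astrocyte-like share was 6.70% in uninjured cord, 1.69% at 0.5 days, 0.0108% at 3 days and 0.329% at 7 days. The pan-reactive list was then at 3.50, 3.60, 3.27 and -0.80 at 0.5, 1, 7 and 90 days, the homeostatic astrocyte list at -0.95 at 0.5 days and 0.61 at 90 days, and the homeostatic microglia list at -2.29, -1.82, -1.70, -1.78, -1.74, -1.53 and -1.09 from 0.5 to 90 days. With a minimum of 200 genes the share was 3.01%, 2.84%, 0.283% and 0.747% at 0.5, 1, 3 and 7 days, the pan-reactive list 6.21 and 5.06 at 1 and 7 days, the homeostatic astrocyte list -1.64 at 7 days, and the microglia list -2.02, -1.90 and -1.37 at 1, 14 and 90 days. With at most 10% mitochondrial UMIs the share was 1.48%, 0.279% and 0.472% at 1, 7 and 90 days, the pan-reactive list 6.28 at 1 day and the homeostatic astrocyte list -0.85 and -1.43 at 1 and 7 days. With no doublets left out the share was 19.9% in uninjured cord and 0.115% at 3 days, the pan-reactive list 5.47 and the homeostatic astrocyte list -0.77 at 0.5 days and -0.86 at 1 day, and the microglia list -2.02 and -1.89 at 7 and 14 days. Leiden resolution 2 gave the microglia list -1.97, -1.54, -1.84, -1.20 and -0.91 at 1, 3, 14, 60 and 90 days.

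Median-ratio scaling gave the pan-reactive list 4.55, 5.26 and 4.83 at 0.5, 1 and 7 days, the homeostatic astrocyte list -1.02, -1.25, -1.96 and 0.064, and the microglia list -1.94, -1.65, -1.38, -1.43, -1.32 and -1.01 from 1 to 90 days. A pseudocount of 5 CPM gave the pan-reactive list 4.28, 4.43, 4.51 and -0.51, by construction nearer 0 for genes near the floor, and the microglia list -1.92 and -1.90 at 3 and 7 days. Free-RNA correction gave the pan-reactive list 5.52, 6.37 and 6.21 and the homeostatic astrocyte list -0.34, -0.57, -0.86 and 0.35. Leaving out the highest cell gave the pan-reactive list 5.93, 6.25 and 0.94 at 0.5, 1 and 90 days and the homeostatic astrocyte list 0.53 at 90 days. Members with at least 50 UMIs gave the pan-reactive list 6.31 at 1 day. Members that are not naming markers gave the homeostatic astrocyte list -0.89 and -1.64 at 1 and 7 days and the microglia list -1.78, -2.40, -1.87, -2.17, -1.91, -1.68 and -1.38 from 0.5 to 90 days. Thinned cells gave the homeostatic astrocyte list -0.56, -0.56 and -0.85, the pan-reactive list 1.12 at 90 days, and the microglia list -2.12, -1.37, -1.58, -1.70, -1.15 and -0.83 from 1 to 90 days. Female-called cells gave the homeostatic astrocyte list -0.54 and -0.96 at 0.5 and 1 day and the microglia list -2.41, -2.15, -2.25, -2.16, -1.85 and -1.35 at 0.5, 1, 3, 7, 60 and 90 days. Male-called cells gave the pan-reactive list 3.74 and 4.69, the homeostatic astrocyte list -0.82 and -0.47 at 0.5 and 1 day, and the microglia list -2.64, -1.87, -1.93, -1.84 and -1.49 at 0.5, 1, 3, 7 and 90 days. The first naming rule put the microglia-like share at 0.5 days at 0.407%, because it leaves cluster 4 unnamed, and the microglia list at -1.69, -2.03 and -1.31 at 0.5, 1 and 90 days.

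Values that were reversed, as defined above, are given next, and for each the cause was not tested. Changes of sign that fall short of that definition are left out. Examples are the pan-reactive list at 90 days, the endothelial-like angiogenic list at 1 day and Slc1a2 in astrocyte-like cells at 7 days. With 1000 genes: microglia-like glycolysis -0.094 at 7 days and chemokines -0.17 at 90 days, and in astrocyte-like cells Slc1a2 -0.18 at 0.5 days and Lcn2 -0.68 and -0.043 at 7 and 90 days. With at most 10% mitochondrial UMIs: Slc1a2 -0.17 at 1 day. With no doublets left out: astrocyte-like MHC class II -0.36 at 7 days and Slc1a2 -0.059 at 1 day. With median-ratio scaling: Slc1a2 -0.16 and -0.46 at 0.5 and 1 day. With the first naming rule: ependymal-like interferon -0.24 at 1 day, OPC-like proliferation 0.79 at 0.5 days and Apoe in microglia-like cells 1.13 at 0.5 days. With female-called cells: OPC-like proliferation 0.97 and -0.028 at 0.5 and 14 days, chemokines -0.11 at 7 days, MHC class I -0.19 and class II -0.23 at 14 days, oligodendrocyte-like interferon -0.20 at 1 day and MHC class II -0.44 at 7 days, and Slc1a2 -0.21 at 1 day. With male-called cells: microglia-like interferon -0.14 and -0.62 at 60 and 90 days, proliferation -0.31 and chemokines -0.19 at 90 days, and OPC-like chemokines -0.021 at 7 days. With members of at least 50 UMIs: OPC-like proliferation 0.42 and endothelial-like angiogenic genes -1.11 at 0.5 days, and oligodendrocyte-like lipid handling -0.31 at 60 days. With thinned cells: OPC-like chemokines -0.41 at 7 days and lipid handling -0.16 at 14 days, oligodendrocyte-like cholesterol 0.039 at 1 day and lipid handling -0.20 at 60 days, and S100b 0.020 at 1 day. With free-RNA correction: oligodendrocyte-like MHC class II -0.38 at 1 day and interferon -0.015 at 7 days, and Vim in astrocyte-like cells -0.44 at 0.5 days.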

Other observations

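Oligodendrocyte-like cells were compared by the same lists, although the class was added after the data had been seen. They had higher immediate early and heat shock genes at every time and cholesterol synthesis at -1.09 or lower from 3 days on. Immediate early and heat shock genes lay at 3.81, 2.33, 1.31, 1.76, 2.09, 0.95 and 0.82 from 0.5 to 90 days. Genes of cholesterol synthesis lay at -0.17, -0.31, -1.09, -1.55, -2.18, -1.92 and -1.40. At 7 days the cholesterol list lay below 0 in astrocyte-, microglia-, ependymal- and OPC-like cells too, so its fall is not particular to this class. Hmgcs1 was 8.28-fold lower at 14 days, and Mvd was 15.8-fold lower at 60 days. These genes were chosen by the rule for lists. At 0.5 days the redox enzyme gene Srxn1 was 275-fold (126 to 750), the stress gene Gadd45b 270.5-fold (92.5 to 1312) and the kallikrein Klk9 236-fold (65.3 to 1949) higher. Most of the class at that time (82.8%) is cluster 23, which Cryab, Srxn1, Klk9 and Mt2 lead, so that cluster may be that library rather than a type; the same class lay at 0.04 for cholesterol at 1 day after thinning.

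In the same class Serpina3n was 75.9-fold, 125-fold, 79.9-fold and 47.9-fold higher at 1, 3, 7 and 14 days, and Klk8, another kallikrein, 84.6-fold and 86.8-fold at 3 and 7 days. Fxyd7, a sodium pump regulator, was at least 80.7-fold and 95.8-fold higher at 7 and 14 days. Il33, an alarm cytokine, was 7.46-fold and 8.48-fold higher at 60 and 90 days. MHC class I genes lay at 0.81, 0.87, 0.94, 1.00, 0.89, 0.68 and 1.44 from 0.5 to 90 days, with H2-D1 13.4-fold higher at 90 days. Lower were Jph4 (24.0-fold and 13.5-fold at 0.5 and 1 day) and Hopx (35.4-fold at 3 days). The libraries hold 79 to 1025 such cells, and 229 in uninjured cord.

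The matrices list a GFP feature, which no comparison uses. The labels name no reporter strain, so the origin of its UMIs is not known. It took 60.3 CPM of all kept UMIs in uninjured cord and 49.5, 26.5, 11.3, 34.2, 25.6, 20.5 and 9.60 CPM from 0.5 to 90 days.

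Among cells with either Xist or Y-linked UMIs but not both, those with Y-linked UMIs made up 18.8% in uninjured cord, 59.6%, 50.8%, 31.1% and 38.6% at 0.5 to 7 days, 0.0124% at 14 days and 43.1% and 43.4% at 60 and 90 days. After thinning to 1000 UMIs, B/plasma-like cells with a pre-B gene (Vpreb1, Igll1, Rag1 or Dntt) were 1.27%, 10.8%, 7.01%, 5.79%, 17.0%, 11.6%, 15.8% and 20.9% from uninjured to 90 days.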
